A study of Rattus norvegicus with 4 samples.

How the data were processed

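Ribosome profiling libraries of neonatal rat ventricular cardiomyocytes were analysed, 2 from cells treated with phenylephrine (PE) and 2 from untreated controls. Groups and replicate numbers were taken from the sample titles, because the treatment text of the labels mentions PE for all 4 libraries. Per the labels' protocols, cells were washed with cycloheximide, which halts elongating ribosomes, lysates were digested with RNase I, monosomes were recovered on spin columns, ribosomal RNA was removed and short fragments were cut from a gel and sequenced. Per the submitters' processing notes, cutadapt 2.0, Bowtie 1.1.2, STAR 2.4.2a and the Rnor_6.0 genome were used. The ORF caller and the program that counted footprints are not given in the sources used here.

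The authors deposited raw counts of footprints per ORF, as whole numbers for 18847 ORFs in each library, and an annotation of the same ORFs. Per the file headers, that annotation gives the authors' own DESeq2 comparison, with log2 fold changes, p-values and adjusted p-values. It also gives a normalized mean count over libraries, a coverage signal deposited by the authors that was used only to identify the table's scale. Per the file headers it further holds ORF class, gene name, coordinates, amino acid sequence and the number of P-sites, the positions of the ribosome's peptidyl site, in each reading frame, pooled over libraries. Of 64444083 P-sites, 84.7% were in frame 0. Per-sample columns left unused numbered 0. Coordinates are 1-based on Rnor_6.0 and run from the start to the stop of an ORF, introns included.

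Library totals over all ORFs were 11446574 and 13827599 for control and 12117629 and 12537740 for PE. Of the ORFs, 3172 had 0 counts in all libraries. Counts and P-sites did not always go together. The median ORF had 1.17 counts per P-site, 1290 tested ORFs had under 0.5, and 1807 annotated ORFs had 0 counts, and a value under 0.5 is stated beside the genes named. Genes such as Actg1, Tpi1 and Hsp90aa1 had P-sites but 0 counts and could not be tested.

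Counts were filtered with filterByExpr, scaled with TMM factors of 0.982 to 1.02 and tested with edgeR 4.0.16 (R 4.3.3), by the robust quasi-likelihood test of PE against control over all 4 libraries without a replicate term. P-values were adjusted by Benjamini-Hochberg over the 12609 ORFs tested, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 2.18%, which lets small changes pass. In counts simulated for 12609 ORFs with the real means and library sizes, of which 12419 passed the filter, 200 ORFs were changed and 90 more were shifted for the list and pair simulations below. The test recovered 56.7% of 1.25-fold, 64.2% of 1.5-fold and 84.8% of 2-fold changes, and 4 of its 181 calls (2.21%) were of unchanged ORFs. Far fewer ORFs were changed there than the 5386 called in the data. The p-value that passes after adjustment depends on that share, so these rates do not carry over to the real comparison.

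For gene lists, 25 lists were fixed before the data were examined, with 1 annotated ORF per gene, the one of highest mean CPM. The 24 lists with at least 3 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. In the simulation, at the preset correlation, a list of 30 genes raised by 0.5 on the log2 scale gave a camera p = 1.6e-34 and an unchanged list p = 0.76. Simulated counts were drawn independently for each ORF, so this does not test the preset correlation, and 1 unchanged list gives no rate of false calls. ORF classes are those of the deposited annotation, and their called shares have exact Clopper-Pearson intervals, which cover counting error only. Pairs of an upstream ORF and the annotated ORF of its gene were formed where each had a mean count of at least 10. For these pairs the difference of log2 fold changes was tested as an interaction of ORF kind and treatment in edgeR. The model had no library term, so the upstream and annotated counts of the same library entered as independent samples. Simulated counts were independent between ORFs, so the simulation does not test this. The simulation recovered 24 of 59 pairs with an upstream ORF raised by 1 and called 3 of 557 unchanged pairs. Set beside the 24 true calls, the 3 false calls are a larger share of calls than the adjusted p threshold aims for. With so few calls, that share is imprecise.

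The named genes followed a rule written before the data were examined. They were the 10 highest and 10 lowest annotated ORFs among those past the threshold with non-overlapping groups and a mean count of at least 20, the 5 highest and 5 lowest ORFs of other classes by the same rule, 8 genes always named (Nppa, Nppb, Acta1, Myh7, Myh6, Atp2a2, Ankrd1 and Rcan1), and up to 4 members of each list with the smallest p in the direction of its median. Further list members, the abundant ORFs, the upstream ORF pairs and the gene families of the closing section were named after their values were seen.

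Alternatives fixed before the data were examined were RLE size factors, library totals only, TMM on annotated ORFs without the mitochondrial genome, no low-count filter, a filter of 20 counts in at least 2 libraries, DESeq2 1.42.0, a replicate block, 1 ORF per gene, a pair mean count of 20, each library left out in turn, and the authors' deposited table. A test against 1.5-fold, a restriction to ORFs with at least 0.5 counts per P-site, and removal of a lowess trend of each library with ORF length were added after seeing the data. Some results under the rule for named genes are not reported here. RNA-seq of the same cells was not analysed here, so translational efficiency was not computed.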

Results

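Neonatal rat ventricular cardiomyocytes, heart muscle cells isolated from Sprague-Dawley rats at postnatal day 2, were compared after exposure to phenylephrine (PE, an α1-adrenergic agonist widely used to make cultured cardiomyocytes grow) at 20 µM for 24 h and without it. Ribosome profiling was the readout: short RNA fragments protected by ribosomes were sequenced and counted on open reading frames (ORFs), so each value reflects both how much mRNA was present and how heavily it was translated. RNA-seq was not analysed here, and the 2 contributions are therefore not separated below. Each group had 2 libraries. The control libraries held 11446574 and 13827599 footprints on listed ORFs and the PE libraries 12117629 and 12537740. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.62 in control and 1.60 in PE, and were counted as separate samples. The labels do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

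PE was followed by higher footprint counts on the natriuretic peptide ORFs Nppa and Nppb and on all 22 tested ORFs of cholesterol synthesis and its regulation. Counts were lower on 26 of 31 ORFs of fatty acid uptake and oxidation. The collagen ORFs Col3a1, Col6a1 and Col6a2 were lower too, within a list of 28 fibroblast and matrix genes that was mixed, with 15 lower and 10 higher. The question was which ORFs changed their ribosome occupancy after PE. Of 12609 ORFs tested, 2696 were higher and 2690 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05. Among them 441 were at least 2-fold higher and 566 at least 2-fold lower. These calls included an annotated ORF of 5111 of the 11286 genes that had one tested. The groups did not overlap in 68.6% of tested ORFs, where chance gives 33.3% for 2 against 2 libraries. Most calls were of modest size: a test against a 1.5-fold change, added after seeing the data, called 459 higher and 550 lower. The number of calls also depended on the method, and DESeq2 called 3446 ORFs.

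Large increases among annotated coding ORFs included those of Il11, Wfdc1 and Bdkrb2. Il11, an interleukin-6 family cytokine (Rnor_6.0 chromosome 1, 72635278 to 72642295), rose 18.1-fold, from 0.208 ± 0.193 to 3.72 ± 0.657 CPM (counts scaled to library size by TMM; SD, n = 2), with an adjusted p = 6.2e-08 in edgeR's quasi-likelihood test. Wfdc1, a secreted protein with a whey acidic protein domain (chromosome 19, 52314075 to 52330979), rose 15.6-fold, from 2.71 ± 0.913 to 41.7 ± 3.69 CPM. Bdkrb2, the bradykinin B2 receptor (chromosome 6, 129423251 to 129427072), rose 11.2-fold, from 6.59 ± 0.0615 to 73.9 ± 3.05 CPM. Hsf2bp rose 13.4-fold, the IgE receptor gene Fcer2 11.4-fold, carbonic anhydrase Car4 10.8-fold, the receptor-modifying protein Ramp3 10.7-fold and the synaptotagmin Syt12 10.0-fold. The fast skeletal myosin light chain Myl1 rose 11.5-fold, although only 0.403 counts were assigned to it per P-site of the deposited annotation, where the median ORF had 1.17.

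Large decreases were on ORFs that had low to moderate counts in control. The chemokine Cxcl13 was 30.5-fold lower. Dhrs7c, a sarcoplasmic reticulum dehydrogenase of striated muscle, was 30.3-fold lower, from 30.2 ± 3.93 to 0.987 ± 0.213 CPM (SD, n = 2), with an adjusted p = 9.0e-20 in edgeR's quasi-likelihood test. The kelch-like gene Klhl33 (chromosome 15, 27813393 to 27815261) fell 26.1-fold, and AC130146.1, listed next to it at 27818627 to 27819376, fell 23.0-fold. Klhdc7a was 22.5-fold lower, the axonemal dynein Dnah11 21.7-fold, the tenascin Tnn 21.0-fold and the nephrin gene Nphs1 12.2-fold, and Asb14, an ankyrin repeat and SOCS box protein, had a log2 fold change of -3.59 ± 0.28 (SE).

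Among ORFs with at least 500 CPM on average, a group examined only after the values were seen, the oxygen carrier myoglobin (Mb) had the largest change in size: 1313 ± 10.7 CPM in control and 337 ± 1.85 CPM in PE, a log2 fold change of -1.96 ± 0.02. The proteoglycan Gpc3 followed among the decreases outside the lists below, with -1.62 ± 0.03. Scd2, a fatty acid desaturase, rose by 1.29 ± 0.02.

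Genes long used as markers of cardiomyocyte hypertrophy mostly rose. Nppa, the precursor of atrial natriuretic peptide (chromosome 5, 164808483 to 164809437), went from 4899 ± 105 to 17811 ± 83.4 CPM (SD, n = 2), 3.64-fold, and Nppb, the B-type precursor (chromosome 5, 164796286 to 164797326), from 2093 ± 27.1 to 5240 ± 81.2 CPM, 2.50-fold. The adjusted p were 2.6e-40 and 5.8e-35 in edgeR's quasi-likelihood test. Ankrd1, a stress-responsive cardiac ankyrin repeat protein, rose 1.42-fold from 11263 ± 44.0 CPM, Rcan1, an inhibitor and target of calcineurin, 1.56-fold, and skeletal α-actin Acta1 1.17-fold. Timp1, an inhibitor of matrix metalloproteinases, rose 3.32-fold.

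Both myosin heavy chains of the ventricle were among the genes named in advance. Myh7, the β form (chromosome 15, 33634529 to 33656081), was the most abundant of these 8 genes, at 32088 ± 59.7 CPM in control and 30803 ± 122 CPM in PE. Its log2 fold change of -0.06 ± 0.01 passed the test, with an adjusted p = 1.5e-05 in edgeR's quasi-likelihood test, but lost it without PE replicate 1 (adjusted p = 0.089) or PE replicate 2 (adjusted p = 0.088). It turned to 0.14 once the trend with ORF length described below was removed. Myh6, the α form (chromosome 15, 33605721 to 33629211), fell from 6593 ± 34.2 to 2654 ± 53.3 CPM, 2.48-fold, with 0.190 counts per P-site. Atp2a2, the sarcoplasmic reticulum calcium pump, had a log2 fold change of -0.53 ± 0.11, but with 0.00452 counts per P-site its 28.8 CPM in control are a small remainder of its footprints.

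**Figure D1:**
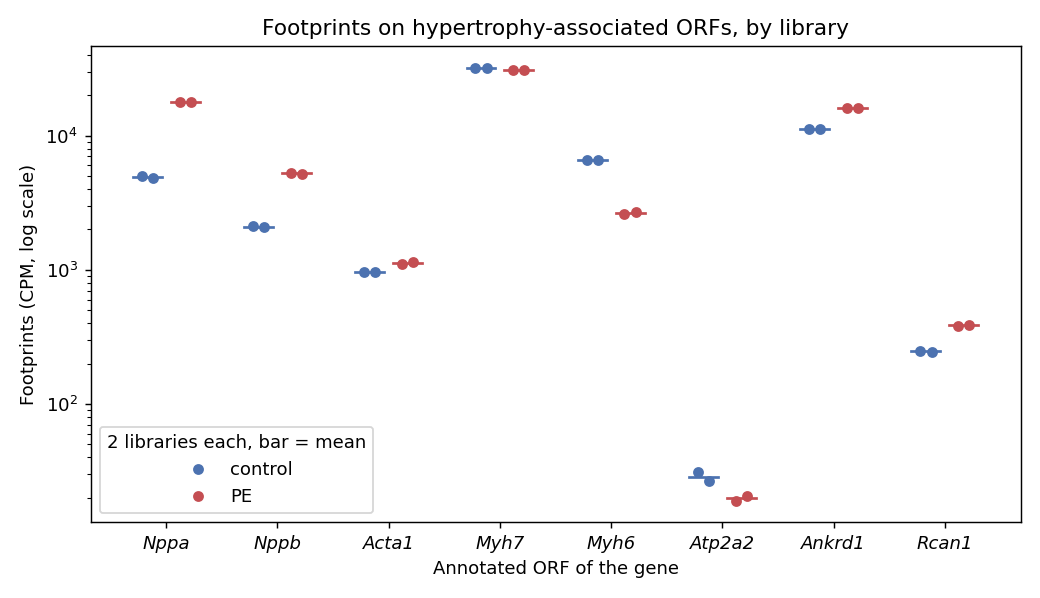
Footprints in CPM (log scale) on the annotated ORF of the 8 genes named in advance, with 1 point per library and a bar at the mean of the 2 libraries of each group. Nppa rose from 4899 to 17811 CPM and Myh6 fell from 6593 to 2654 CPM, while Myh7 lay at 32088 and 30803 CPM; Atp2a2 is barely counted.

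Of the 15 tested genes of the fetal and hypertrophy list, 13 were higher and 1 lower (13 and 1 adjusted over the list alone). Besides those above, the receptor Tnfrsf12a rose by 1.39 on the log2 scale, the growth factor Hbegf by 0.97 and Bdnf by 1.39, while Gdf15 had -0.06 and did not pass. The LIM protein Fhl1 rose by 1.27, with 0.0938 counts per P-site. The list stood above other genes in camera with a preset correlation of 0.01 (adjusted p = 3.1e-39), a call that was lost with an adjusted p = 0.17 with an estimated correlation. None of the 12 lists called with the preset correlation kept its call with an estimated one. That version of the test rests on the few residual degrees of freedom of 4 libraries, so the losses do not show that members were correlated. Among these lists, fatty acid oxidation had an estimated correlation of -0.015, below the preset, and cholesterol 0.43, above it.

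Among 18 genes of α1-adrenergic and MAP kinase signalling, 10 were higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.0040; adjusted p = 0.30 with an estimated correlation). The list consists mostly of feedback inhibitors. Among its increases were Rgs2, which limits Gq signalling, by 1.82 ± 0.06 (log2, SE), and the MAP kinase phosphatases Dusp4 by 1.05 ± 0.07 and Dusp6 by 0.91 ± 0.07. The α1-adrenergic receptors parted, with Adra1a higher by 0.73 and Adra1b and Adra1d at -1.20 and -2.55. Of 16 immediate-early genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.057; adjusted p = 0.30 with an estimated correlation). Nr4a3 rose by 2.33 ± 0.32, Fos by 1.21 ± 0.11 and Junb by 0.65 ± 0.05, and Ier3 rose 2.38-fold, while Egr1 had -0.06 and Atf3 -0.14 and did not pass. Leaving out control replicate 1, control replicate 2 or PE replicate 1 made it a call, with adjusted p of 0.046, 0.010 and 0.045 in camera.

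Contractile genes went both ways. Of 30 sarcomere genes, 12 were higher and 17 lower (12 and 17 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.41). The intermediate filament desmin (Des) rose by 0.93, troponin C (Tnnc1) by 0.68 and cardiac actin (Actc1) by 0.51 on the log2 scale. The M-band proteins Myom2 and Myom1 fell by 0.75 ± 0.01 and 0.49 ± 0.02 (SE) and the Z-disc protein Nebl by 0.66 ± 0.02. Tropomyosin Tpm1 fell by 0.91 with 0.00213 counts per P-site, a change that rests on a small part of its footprints.

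Calcium handling and ion channel genes were mostly lower, with 15 of 26 lower and 6 higher (15 and 6 adjusted over the list alone; camera adjusted p = 0.0038; adjusted p = 0.21 with an estimated correlation). The ryanodine receptor Ryr2 fell from 1892 ± 23.7 to 1036 ± 0.670 CPM (SD, n = 2), 1.83-fold. The L-type calcium channel Cacna1c fell 2.22-fold, the calcium-binding protein Hrc 2.69-fold, connexin 43 (Gja1) 1.63-fold, and phospholamban (Pln), the peptide inhibitor of the calcium pump, 1.39-fold. Connexin 40 (Gja5) went the other way, with a log2 fold change of 1.87.

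Of 26 genes of the actin and tubulin cytoskeleton and targets of serum response factor, 11 were higher and 7 lower (11 and 7 adjusted over the list alone; camera adjusted p = 0.0042; adjusted p = 0.30 with an estimated correlation). The Z-disc adaptor Pdlim5 rose 1.93-fold, from 970 ± 12.7 to 1876 ± 18.9 CPM, α-actinin 1 (Actn1) 1.58-fold and β-tubulin Tubb5 1.33-fold, and tropomyosin 4 (Tpm4) by 0.59 on the log2 scale. The filamins Flna and Flnc fell by 0.53 and 0.39 on the log2 scale and β-actin (Actb) by 0.35.

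Of 45 translation factors, 29 were higher and 1 lower (29 and 1 adjusted over the list alone; camera adjusted p = 1.7e-04; adjusted p = 0.20 with an estimated correlation). The elongation factors Eef1d, Eef1a2 and Eef2 rose 1.42-fold, 1.29-fold and 1.20-fold, and Eef1g 1.64-fold with 0.344 counts per P-site. The member that fell was Eef2k, the kinase that inhibits Eef2, by 0.61. Of 42 ribosomal protein genes, 30 were higher and 1 lower (33 and 1 adjusted over the list alone; camera adjusted p = 2.8e-04; adjusted p = 0.29 with an estimated correlation). Rpl3 rose 1.39-fold, Rpl23 1.33-fold and Rpl35 1.83-fold, the last with 0.316 counts per P-site. Of these 42 genes, 34 had under 0.5 counts per P-site, and of the other 8, 6 were higher and 0 lower by edgeR's quasi-likelihood test. Of 43 nucleolar ribosome biogenesis genes, 13 were higher and 3 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.28), with Rrp12 up 1.51-fold and the RNA polymerase subunit Polr1c up 1.48-fold.

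Of 12 cytosolic heat shock genes, 9 were higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 1.7e-04; adjusted p = 0.20 with an estimated correlation). Hspb7 and Hsph1 both rose 1.60-fold or more, to 1224 ± 40.3 and 442 ± 6.05 CPM, Hspb1 rose 1.32-fold and αB-crystallin (Cryab) 1.27-fold, and Bag3 fell by 0.40 on the log2 scale. Of 22 endoplasmic reticulum chaperone and unfolded protein response genes, 10 were lower and 5 higher (10 and 5 adjusted over the list alone; camera adjusted p = 0.063; adjusted p = 0.41 with an estimated correlation). BiP (Hspa5) fell 1.31-fold from 3382 ± 28.2 CPM, Herpud1 1.72-fold, Hyou1 1.32-fold and calreticulin (Calr) 1.17-fold. That list passed with library totals alone (adjusted p = 0.018 in camera), without control replicate 1 (adjusted p = 0.046) and with DESeq2 statistics (adjusted p = 0.046). The 33 tested genes of the ATF4 and amino acid list were split, with 10 higher and 10 lower (11 and 14 adjusted over the list alone; camera adjusted p = 0.71). The amino acid transporters Slc3a2 and Slc7a11 fell by 0.32 and 0.78 on the log2 scale, and the serine synthesis enzyme Phgdh was 1.36-fold lower.

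Every tested gene of cholesterol synthesis and its regulation was higher. All 22 passed (22 adjusted over the list alone), with a mean log2 fold change of 1.22 (camera adjusted p = 5.2e-68; adjusted p = 0.20 with an estimated correlation of 0.43 between members). The synthase Hmgcs1 (chromosome 2, 52436356 to 52443466) rose from 752 ± 28.1 to 2296 ± 28.3 CPM (SD, n = 2), 3.06-fold, with an adjusted p = 6.7e-34 in edgeR's quasi-likelihood test. Squalene synthase Fdft1 rose 2.77-fold and the isomerase Idi1 4.10-fold, from 162 ± 5.18 to 664 ± 10.1 CPM. The transcription factor Srebf2 rose by 0.51 on the log2 scale, and Cyp51 rose 2.82-fold.

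Of 31 tested genes of fatty acid uptake and oxidation, 26 were lower and 1, the long-chain dehydrogenase Acadl at 0.11, was higher (26 and 3 adjusted over the list alone; camera adjusted p = 1.6e-19; adjusted p = 0.17 with an estimated correlation). Ech1 fell from 618 ± 5.07 to 237 ± 2.43 CPM (SD, n = 2), 2.60-fold, lipoprotein lipase (Lpl) 2.26-fold, and the carnitine palmitoyltransferase Cpt1b 1.95-fold, while the trifunctional protein subunit Hadhb fell by 0.58 on the log2 scale. The regulators Ppara and Ppargc1a fell by 1.06 and 0.90 on the log2 scale.

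Of 74 nuclear-encoded respiratory chain and ATP synthase genes, 30 were lower and 17 higher (31 and 18 adjusted over the list alone), and the list was not called (camera adjusted p = 0.052; adjusted p = 0.39 with an estimated correlation). Cox8b, a muscle form of a cytochrome oxidase subunit, fell 3.08-fold, Ndufa4 1.34-fold, succinate dehydrogenase subunit Sdha 1.28-fold and Atp5f1a 1.14-fold. These are short ORFs, with a median of 423 nt, and after removal of the trend with ORF length 47 were lower and 4 higher (adjusted p = 3.2e-06 in camera). The list was also called with RLE size factors (adjusted p = 0.050), library totals (adjusted p = 0.0054), no low-count filter (adjusted p = 0.048), DESeq2 statistics (adjusted p = 0.046) and without control replicate 2 (adjusted p = 0.037). The 4 tested ORFs of the mitochondrial genome had a median length of 180 nt. Of these, 1, a short ORF listed under Mt-nd5, was higher (2 adjusted over the list alone; camera adjusted p = 0.71). Its value is that of this ORF and not of the gene as a whole. This ORF no longer passed after removal of the length trend (adjusted p = 0.055 in edgeR's quasi-likelihood test).

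Of 20 genes of glycolysis and glucose transport, 12 were higher and 6 lower (13 and 6 adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.39 with an estimated correlation). The phosphofructokinase Pfkp rose 1.72-fold, the lactate exporter Slc16a3 2.13-fold, Pgam1 1.58-fold and Ldha 1.63-fold, the last 2 with 0.465 and 0.165 counts per P-site. The muscle forms Pgam2 and Pfkm fell by 2.34 and 0.63 on the log2 scale, and the insulin-responsive glucose transporter Slc2a4 by 1.15. The call of the list was lost with library totals alone (adjusted p = 0.054 in camera) and among ORFs with at least 0.5 counts per P-site (adjusted p = 0.74).

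**Figure D2:**
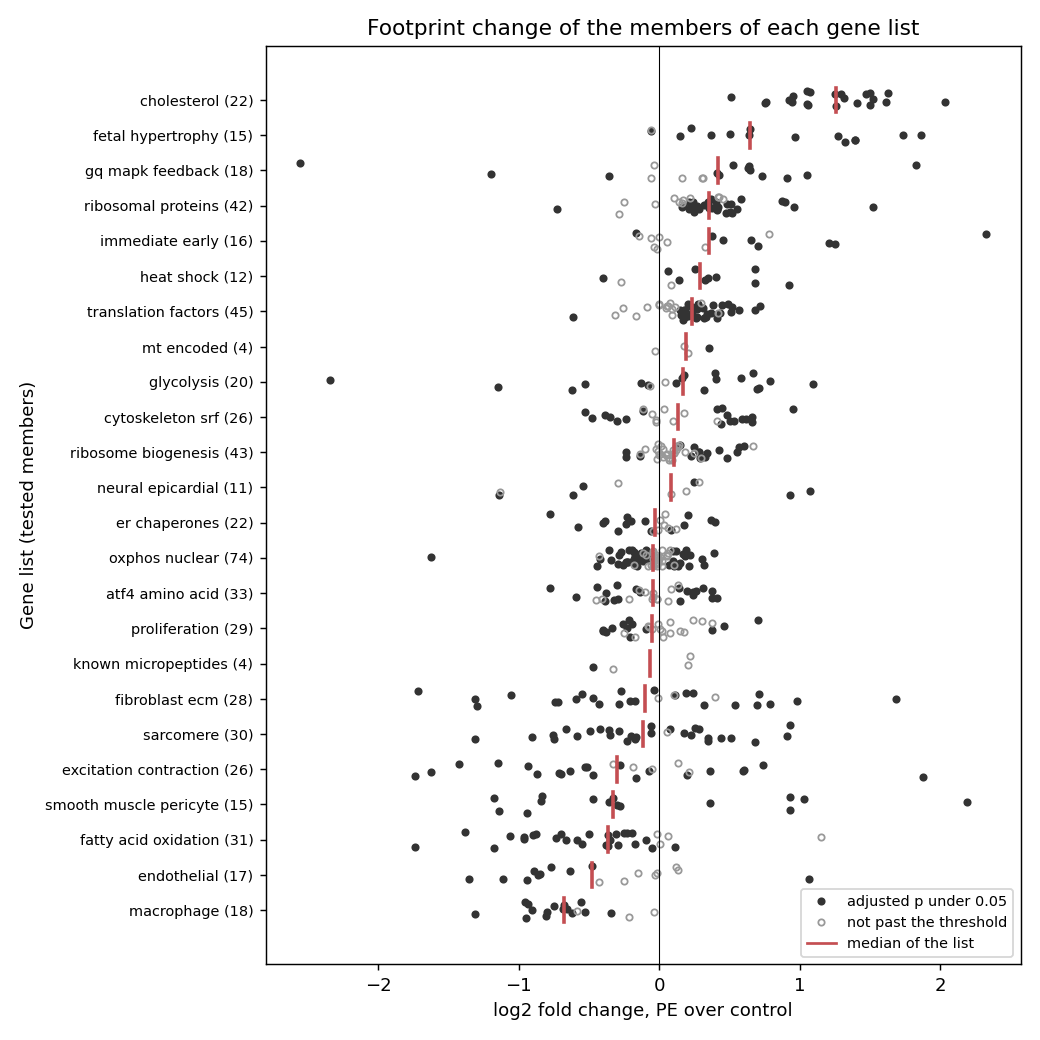
Log2 fold change (PE over control) of each tested member of the 24 gene lists with at least 3 tested genes, 1 point per gene, filled where the adjusted p passed 0.05, with a red bar at the list's median. All 22 cholesterol genes lie above 0 and 15 of 18 macrophage markers are filled points below it, while sarcomere genes spread to both sides.

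Markers of other cell types the culture could hold were measured as well, since the labels describe plating to remove cells that are not cardiomyocytes. Of 18 macrophage and leukocyte markers, 15 were lower and 0 higher (15 and 0 adjusted over the list alone; camera adjusted p = 1.2e-04; adjusted p = 0.20 with an estimated correlation). The mannose receptor Mrc1 fell 1.88-fold, from 142 ± 4.27 to 75.4 ± 3.60 CPM (SD, n = 2), CD45 (Ptprc) 1.94-fold, Laptm5 1.75-fold and lysozyme (Lyz2) 1.47-fold. Of 17 endothelial markers, 9 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.065; adjusted p = 0.30 with an estimated correlation), with VE-cadherin (Cdh5) 1.92-fold lower, Emcn 2.16-fold, Esam 1.86-fold and Erg 2.56-fold. Leaving out either control library made that list a call (adjusted p = 0.047 without control replicate 1 and 0.021 without control replicate 2 in camera).

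Fibroblast and matrix genes parted. Of 28 tested, 15 were lower and 10 higher (15 and 11 adjusted over the list alone; camera adjusted p = 1.3e-06, downward; adjusted p = 0.21 with an estimated correlation). Type III collagen (Col3a1; chromosome 9, 52023399 to 52058948) fell 3.29-fold, from 7735 ± 101 to 2348 ± 18.7 CPM (SD, n = 2), periostin (Postn) 2.08-fold, and the type VI collagens Col6a1 and Col6a2 2.49-fold and 2.46-fold. Fibulin 2 (Fbln2) rose by 1.68, fibronectin (Fn1) by 0.79 and decorin (Dcn) by 0.70 on the log2 scale. Of 15 smooth muscle and pericyte markers, 10 were lower and 5 higher (10 and 5 adjusted over the list alone). Their median of -0.33 and mean of -0.08 were below 0 while camera placed the list above other genes without calling it (adjusted p = 0.28). Tagln fell 1.78-fold, Mylk 2.21-fold, Acta2 1.23-fold and Myl9 1.26-fold, and calponin (Cnn1) rose by 2.19.

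Of 11 Schwann cell, neuron and epicardial markers, 3 were higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.84), with a median of 0.08 and a mean of -0.08. Uchl1 rose 1.90-fold, Krt18 2.11-fold with 0.272 counts per P-site, and Tubb3 1.19-fold, a call lost without PE replicate 2 (adjusted p = 0.32 in edgeR's quasi-likelihood test) and in DESeq2 (adjusted p = 0.099). Of 29 cell cycle genes, 10 were lower and 3 higher (10 and 3 adjusted over the list alone; camera adjusted p = 0.71). Pcna fell 1.20-fold, the helicase subunits Mcm7 and Mcm2 1.32-fold each, and Mki67 1.26-fold, while cyclin D1 (Ccnd1) rose by 0.70. After removal of the length trend 5 were lower and 3 higher, the list's median went from -0.06 to 0.05, and the Mki67 call was lost (adjusted p = 0.50 in edgeR's quasi-likelihood test). Of 4 genes of known short peptides, 1 was lower, phospholamban (1 adjusted over the list alone; camera adjusted p = 0.18), and sarcolipin (Sln) had -0.33 ± 0.31 and did not pass.

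Footprint change went with ORF length. Across the 11402 tested annotated ORFs, which are not independent replicates, the Spearman correlation of log2 fold change with length was -0.193. The median log2 fold change was 0.12 among 232 ORFs above 150 and up to 300 nt and -0.25 among 284 ORFs over 6000 nt. The replicate differences within control and within PE correlated with length at -0.0040 and 0.0148. With the trend removed, 24 of 42 ribosomal protein genes were higher and 3 lower (adjusted p = 0.011 in camera), and 15 of 26 calcium handling and ion channel genes lower and 7 higher (adjusted p = 0.017 in camera).

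**Figure D3:**
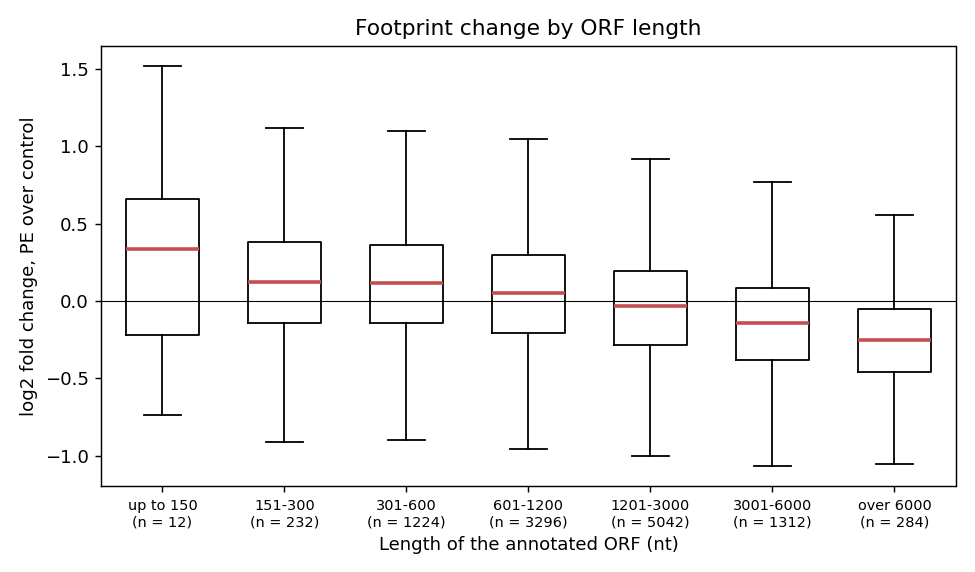
Log2 fold change (PE over control) of tested annotated ORFs by ORF length in nt, as boxes of the quartiles with the median in red, whiskers to the last value within 1.5 times the quartile range and the number of ORFs under each box. The median runs from 0.12 between 150 and 300 nt to -0.25 over 6000 nt; the shortest class holds 12 ORFs.

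ORFs outside the annotated coding sequences carried a small part of the footprints. Upstream ORFs, which lie in the 5′ leader, made up 0.258% of counts in control and 0.290% in PE, and ORFs listed as unannotated, mostly on genes typed as lincRNA, pseudogene or processed transcript, 0.382% and 0.309%. Of 724 upstream ORFs tested, 97 were higher and 41 lower, a called share of 19.1% (95% exact interval 16.3 to 22.1%), against 45.0% of annotated ORFs. Of 203 unannotated ORFs, 24 were higher and 40 lower. Of 147 upstream ORFs that overlap the coding sequence 19 were higher and 7 lower, of 84 downstream ORFs in the 3′ untranslated region 12 and 6, of 29 downstream ORFs that overlap the coding sequence 3 and 5, and of 20 internal ORFs 3 and 2. Against annotated ORFs matched on count, no class differed in its called share by Fisher's exact test with Benjamini-Hochberg adjustment, where the lowest adjusted p was 0.26 and the lowest unadjusted p, for unannotated ORFs, was 0.044. The 259 calls outside annotated ORFs fell to 99 in DESeq2.

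Among these ORFs the largest increase was on a downstream ORF of Nppa (chromosome 5, 164809574 to 164809636), which rose 8.04-fold, a log2 fold change of 3.01 ± 0.23 (SE), with an adjusted p = 1.5e-12 in edgeR's quasi-likelihood test. Upstream ORFs of the cytokine receptor subunit Csf2rb and of Bmp2 rose 3.66-fold and 3.47-fold, one of Prrg4 by 2.14 on the log2 scale and a downstream ORF of S100a4 3.49-fold. An upstream ORF of the orphan receptor Gpr22 fell 3.81-fold. The unannotated ORFs of AABR07052523.2 (chromosome 3), AABR07025277.1 (chromosome 16) and AABR07017145.1 (chromosome 15) fell 3.63-fold, 3.56-fold and 3.48-fold, and one at Rpl13a 3.23-fold with 0.0166 counts per P-site.

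Most upstream ORFs had a higher log2 fold change than the annotated ORF of the same gene. This comparison asks whether footprints moved between the leader and the coding sequence of an mRNA, and its difference does not depend on the amount of that mRNA where both ORFs lie on the same transcripts. In 657 pairs from 572 genes the upstream ORF had the higher log2 fold change in 65.3%. With 1 pair kept per gene, that of the upstream ORF with the most counts, the median difference over genes was 0.18 (95% bootstrap interval 0.13 to 0.23). The mean of the same differences, 0.17, had a sign-flip permutation p = 0.0001, the smallest that 10000 flips can give. The interval and this p treat genes as independent and leave out the spread between libraries, so a shift shared by many genes of a library is not excluded by them. By the interaction of ORF kind and treatment in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 24 pairs differed, 20 with the upstream ORF above and 4 below. That model had no library term and treated the upstream and annotated counts of the same library as independent samples. Its adjusted p and the number of calls therefore do not account for this pairing.

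At Ucp2, the gene of a mitochondrial uncoupling protein, both rose on the log2 scale, the upstream ORF (chromosome 1, 165507258 to 165507368) by 1.16 and the annotated ORF by 0.53, a difference of 0.64 ± 0.07 (SE) with an adjusted p = 4.7e-15 in edgeR's quasi-likelihood test. The zinc transporter Slc39a7 had 1.42 upstream and -0.18 on the annotated ORF, and the small muscle protein Smpx 0.37 and -0.15. The cardiac transcription factors Gata4 and Nkx2-5 had upstream ORFs that rose by 0.62 and 0.97 beside 0.09 and 0.10 on their annotated ORFs. The pairs with the upstream ORF below were those of Dcn, Fzd1, Tspan12 and Hipk3, with differences of -0.46, -0.67, -1.09 and -1.38. The pairs named here were chosen after their values were seen, and their standard errors and adjusted p leave out the pairing of ORFs within a library. The number of calls depended on each library: 14 without control replicate 1, 13 without control replicate 2, 4 without PE replicate 1 and 7 without PE replicate 2. DESeq2 called 45 of the 288 pairs to which it gave an adjusted p. After removal of the length trend the median pair difference was 0.02 in place of 0.19.

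**Figure D4:**
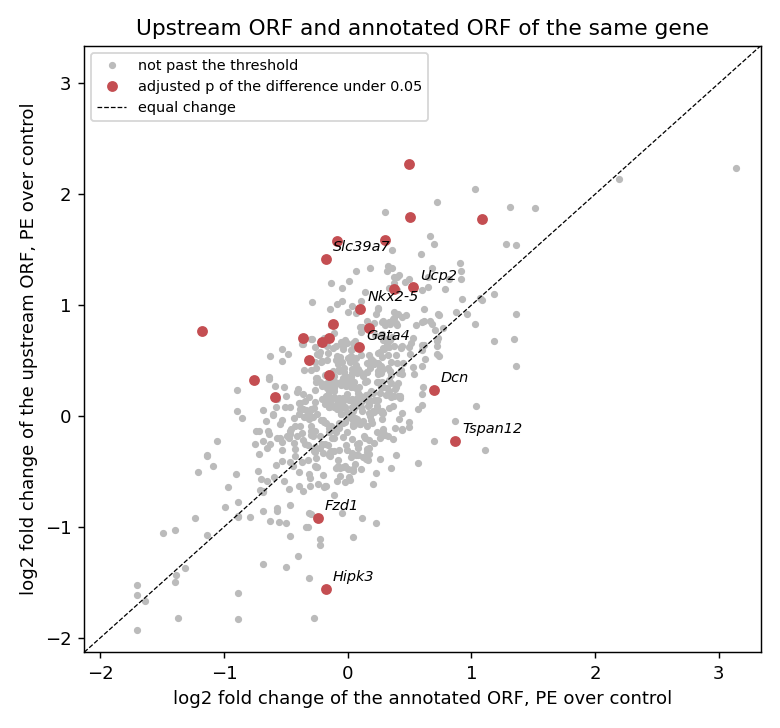
Log2 fold change (PE over control) of the upstream ORF against that of the annotated ORF of the same gene, 1 point per pair for 657 pairs, with pairs whose difference passed an adjusted p of 0.05 in red and a dashed line at equal change. Of the 24 red points, 20 lie above the line, Slc39a7 among them, and 4 below it, those of Dcn, Fzd1, Tspan12 and Hipk3.

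The authors' deposited table of their own DESeq2 comparison called 3417 ORFs at an adjusted p under 0.05, with 1712 higher and 1705 lower in PE. Of these, 3412 were also called here by edgeR's quasi-likelihood test, each in the same direction as in the authors' deposited table. A further 1974 ORFs were called here alone and 5 in the authors' deposited table alone.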

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

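The tests in this part were chosen after the pattern was seen. The deposited annotation reports P-sites for 699 annotated ORFs, each with at least 1000 of them, that have 0 counts in all 4 libraries, which is a signal in columns the comparisons do not use. The most abundant include Tpm1 with 326179 P-sites, Clu with 105598, Hsp90b1 with 90305, Actg1 with 84424, Myl6 with 59732 and Tpi1 with 57211, where 1 listed ORF of such a gene can be at 0 while another of the same gene, as for Tpm1 and Hsp90b1, holds counts.

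Shared footprints are a candidate explanation in both forms tested. Of the 699 ORFs, 60.8% overlapped the span of another listed ORF on the same strand, against 9.39% of 4901 annotated ORFs with as many P-sites and at least 0.8 counts per P-site, and 53.9% had most of their 9-residue peptides in an ORF of another gene, against 1.82%. Together these cover 99.1% of the 699 and 11.1% of the well-counted ORFs, which is consistent with a counting step that left out footprints with more than 1 possible ORF. Which rule the authors used is not given in the sources used here, and no biological explanation was tested, since the ORFs are at 0 in both groups.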

How the results depend on the processing

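Of 1800 recomputed values of named ORFs, 1788 kept their direction and their side of the threshold, and of 384 recomputed gene list tests 345 did. The count of 5386 called ORFs was 5373 with RLE size factors, 5426 with library totals, 5504 without a low-count filter, 5297 with the stricter filter, and 4523 to 4754 with 1 library left out, where the lone library is assumed to vary like the other group. With the replicate block it was 5435, with 23 upstream ORF pairs and 12 lists, and it changed the side of the threshold of no named ORF or list. The labels tie no replicate number to a shared litter or day, and deviations of same-numbered libraries correlated at -0.015 across ORFs. Library totals gave 2333 higher and 3093 lower ORFs. Removal of the length trend gave 5090 calls, lost 778 of the 5386 and turned the sign of 16 of the 4608 called with and without the trend. DESeq2 called 3446 ORFs, 1724 higher and 1722 lower, and 99 outside annotated ORFs in place of 259. Of the 5386, DESeq2 also called 3445 and lost 1941. The authors' table called 3417. Tested against a 1.5-fold change, which asks a stricter question, 1009 passed, 459 higher and 550 lower. Of 12 lists called by camera, 0 were called with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 23. Upstream ORF pairs numbered 24, 4 to 14 with 1 library left out, and 45 in DESeq2. Myh7 turned to 0.14 with the length trend removed, and Wt1, which did not pass, to -0.21 without PE replicate 2 and 0.49 without PE replicate 1. The causes of these changes were not tested. With 2 libraries per group, 64.2% of simulated 1.5-fold changes were recovered. Far fewer ORFs were changed in that simulation than were called in the data, so the rate does not carry over. Upstream ORFs, with a median count of 21.1 against 257 for annotated ORFs, were limited by depth.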

Other observations

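The gene families and tests in this part were chosen only after the results were seen, except the test of the within-gene difference with ORF length, which was written before its result was seen. In the interleukin-6 family, 8 of 12 tested genes were higher and 3 lower (11 adjusted over the list alone; camera adjusted p = 0.034; adjusted p = 0.18 with an estimated correlation). The ligands Il11, Clcf1, Il6 and Lif rose 18.1-fold, 9.88-fold, 8.34-fold and 5.01-fold, with only 95 counts for Il11 and 75 for Clcf1 over all libraries. The ligand Ctf1 had a log2 fold change of -0.67 ± 0.53 (SE) and did not pass. Receptors went both ways, with log2 fold changes of 0.73 for Osmr, 0.34 for Il11ra1, -0.11 for Il6st and -0.82 for Il6r, and Lifr lower too. In fatty acid synthesis and desaturation 12 of 12 genes were higher (12 adjusted over the list alone; camera adjusted p = 9.1e-32; adjusted p = 0.14 with an estimated correlation), among them Fasn by 0.85, Acss2 by 1.37 and Scd by 1.96, the last with 0.233 counts per P-site.

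Of 17 basement membrane genes, laminins and type IV collagens among them, 9 were higher and 7 lower (16 adjusted over the list alone; camera adjusted p = 9.6e-04; adjusted p = 0.14 with an estimated correlation). Lamc1 rose by 0.71, Lamb3 by 0.70, Col4a1 by 0.23 and Col4a2 by 0.21, and Col4a3, Col4a5, Agrn and Lamb2 fell by 1.26, 0.65, 0.79 and 0.57, the last with 0.185 counts per P-site. Of 44 ankyrin repeat SOCS box and kelch-like genes, 17 were lower and 3 higher (21 adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.14 with an estimated correlation), with Klhl33, Asb10, Asb14 and Asb18 at -4.70, -3.90, -3.59 and -1.99. Of 16 tricarboxylic acid cycle genes 8 were lower and 3 higher (12 adjusted over the list alone; camera adjusted p = 0.0036; adjusted p = 0.14 with an estimated correlation), with a median of -0.08. Of 21 chemokines 9 were higher and 9 lower (19 adjusted over the list alone), from -4.93 for Cxcl13 to 3.14 for Ccl27, with a median and mean of -0.21 where camera placed the family above other genes without calling it (adjusted p = 0.15). These p-values come from edgeR's quasi-likelihood test and camera, on families picked for their leading genes.

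Shorter ORFs rose against longer ones in PE, with a Spearman correlation of -0.193 over 11402 annotated ORFs. Footprints shared between ORFs are argued against, since the correlation was -0.184 among 9688 ORFs with at least 0.8 counts per P-site. Whether mRNA level alone could account for it stays open: within genes, the upstream minus annotated difference correlated with the length of the annotated ORF at 0.101 (572 genes; standard error 0.0415; permutation p = 0.018), where a correlation above 0.1 had been set beforehand as the bound against it, which this value passes; the demand that it pass by more than its error was added after the value was seen, and it does not. The standard error and permutation p of the within-gene correlation treat genes as independent and leave out the spread between libraries. A difference in library preparation and an effect of PE cannot be told apart, because the trend with length separates the groups and the labels give no preparation batch. The trends of single libraries were 0.168 and 0.176 in control and -0.167 and -0.179 in PE, and separate the groups by -0.335. They were taken on deviations from the mean of the 4 libraries, so they restate the correlation of the fold change and are no further evidence. The higher values of upstream ORFs over their annotated ORFs may be part of the same trend, as its median went from 0.19 to 0.025 with the trend removed and to 0.039 with the trend held flat up to 150 nt, where only 12 annotated ORFs set it.

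Macrophage markers fell in cultures whose protocol removes cells that attach early. For a lower share of every cell type other than cardiomyocytes, the macrophage median was set against that of fibroblast markers. It lay below it (difference -0.575, permutation p = 0.0058, two-sided, 18 and 28 genes), which passed the bound written against this explanation. That p treats genes as independent and exchangeable between lists of unequal spread (SD 0.30 for macrophage and 0.76 for fibroblast markers). It leaves out the spread between libraries. A further demand, absent from that bound, was that the difference exceed the spread of the fibroblast markers (SD 0.76), and it was not met. This SD is the spread of single genes and not the error of a median. The fibroblast markers ran from -1.72 for Col3a1 to 1.68 for Fbln2, and the explanation stays open. A lower share of macrophages stays open, because the 83.3% of markers called lower are the pattern itself and no test of its source, and the most abundant, Lcp1, had 142 CPM in control. Lower values were not confined to macrophage markers. Of 17 endothelial markers 9 were lower and 1 higher (median -0.48). Of 15 smooth muscle and pericyte markers 10 were lower and 5 higher (median -0.33). An effect of PE on gene activity within macrophages was not tested and stays open too, and of the 18 markers 0 are in another of the lists, while how many cardiomyocytes also express was not examined.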
